A study of Mus musculus with 2 samples.

How the data were processed

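Cells of the choroid and RPE of wild-type ICR mice at 8 weeks of age were profiled in 2 libraries with 10x Chromium 3' v3.1 chemistry. Per the labels, each library pooled 1 male and 1 female mouse, the tissue was digested for 2 h in collagenase A at 1 mg/ml and for 30 min in 0.25% trypsin and passed through a 40 µm filter, and 10000 cells were loaded. The deposited matrices hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger. The version is 4 per the file headers and 2.1.1 per the submitters' processing notes, and the genome build is mm10 per the submitters' processing notes. The gene annotation is not given in the sources used here. The matrices list 1959894 and 1856693 barcodes and 32285 genes, so no cells had been selected in them. For gene positions GENCODE M21 (GRCm38) was used, in which 32158 of the 32285 gene IDs were found (99.6%).

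Barcodes were kept as cells with a UMI minimum at the inflection of the rank curve (841 and 634), bounded to 1000 to 3000 and so set to 1000 in both libraries, with at least 500 genes and at most 20% mitochondrial UMIs. After these limits 8497 and 13401 barcodes remained. Scrublet doublets were removed per library at its automatic threshold, 231 and 727 barcodes, which left 8266 and 12674 cells with a median of 2.69% and 3.05% mitochondrial UMIs. Free RNA was taken from barcodes with at most 100 UMIs, which held 4.90% and 4.11% of all UMIs. Free RNA was left in the counts of the comparisons and subtracted in an alternative, at a share estimated from rod genes for each class and library.

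Counts were scaled to 10000 UMIs per cell and log-transformed in scanpy 1.11.5 under Python 3.11.15. From 2000 variable genes, chosen with library as batch and without panel or mitochondrial genes, 30 principal components and 15 neighbours were computed, and Leiden clustering (leidenalg 0.10.2) at resolution 1.0 gave 29 clusters. Clusters were named from fixed marker lists of 32 cell types. A marker counted as raised at a log2 of at least 2 over the lower-quartile cluster and in at least 10% of cells, at least 3 had to be raised, and a cluster with more markers of another type among its top 10 genes, or with a second type at 0.75 of the best score and 90% of its markers raised, stayed unnamed. Related types, such as fibroblast and chondrocyte, did not count against each other. Fibroblast-like clusters of 2113 and 1018 cells thus kept their name with the chondrocyte marker Chad among their top 10 genes. The endothelial class was clustered again with 1000 variable genes, 20 components and resolution 0.5, and the clusters were named as arterial, capillary or venous, with a marker counted as raised at 0.25 or more of its highest cluster. The form of the naming rule was revised after the clusters were seen. In all, 6 forms were tried for the classes and 4 for the beds, before any panel gene was tested, but with marker tables and class shares under the alternatives in view and, for the beds, the levels of Kdr, Tek, Angpt2, Dll4 and Mfsd2a. The form used is the fifth. The sixth, which allowed 1 foreign gene, was set aside because it was chosen from how the alternatives looked, and was run as an alternative. Under the form used, 1.69% and 2.63% of cells stayed unnamed.

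Counts were summed per library and class for the 11 classes with at least 20 cells in each library. They were fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) using TMM scaling, filterByExpr, robust quasi-likelihood and library as a block, with 10 residual degrees of freedom, a biological coefficient of variation of 0.132 and 15260 genes tested. Each class was set against the equal-weighted mean of the other classes, and the class with the highest mean log2 CPM against the class next to it. The beds were tested in 1 fit with all other classes, each against the mean of the other beds, over 11920 genes. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a log2 fold change of at least 1 in size. Adjustment was over all genes tested for classes and beds and over the panel genes for the highest against the next class. The SE is the size of the log2 fold change divided by the square root of F. CPM values of the classes, beds and named clusters use TMM-adjusted library sizes, while those of unnamed cells, and the marker and Angpt1 ratios between groups of cells, use raw UMI totals and are on another scale. Levels are given as mean and SD of 2 libraries, and single cells were never used as replicates. The 2 classes of the latter test were picked from the same data. Across genes, the libraries correlated with r of 0.751 in rod-like cells to 0.988 in fibroblast-like cells, and genes are not independent replicates.

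The panel held 14 lists with 236 genes, of which 220 were tested. Named genes were set by rule before the data were examined: every measured gene of the angiopoietin and TIE list, and of each other list the 3 genes with the largest log2 fold change over the mean of the others, among those called there, called against the next class and highest in that class in both libraries. For the beds the rule took up to 20 genes with the largest fold change among those called and in the same direction in both libraries. Genes outside this rule are said to be chosen after their values were seen. Results for some single genes of the lists are not reported here. Folds against 0 UMIs are lower bounds from a floor of 3 counts over both libraries. Of 154 pairs of list and class, 121 had the same counts when adjusted over the list alone and the largest difference was 4 genes.

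On simulated data with 100 genes changed 2-fold and 100 changed 4-fold in 1 class, 61% and 81% were found in endothelial-like cells, 66% and 89% in RPE-like cells and 71% and 83% in fibroblast-like cells at an adjusted p below 0.05, without the fold limit. Of 15060 unchanged genes, 10, 11 and 17 passed that threshold, and 3, 2 and 7 were called with the fold limit. The simulated classes shared the same mean profile apart from the changed genes and had no library effect. In the real data 18.1% (endothelial-like) to 28.2% (RPE-like) of genes were called higher in these classes, so the simulated rates need not hold there. The alternatives were other UMI minimums and mitochondrial limits, no or stricter doublet removal, other clustering resolutions, z-scoring within libraries, panel genes in the clustering, other naming forms, at least 50 cells per class, DESeq2 1.42.0 as the test, its size factors in edgeR, no filter on low counts, no replicate block, free RNA subtracted and each library left out. DESeq2 size factors moved the median log2 fold change of all genes by 0.21 in rod-like, 0.15 in B-like, -0.16 in melanocyte-like, -0.14 in endothelial-like and -0.12 in macrophage-like cells. The keratin epithelial-like class was not tested because 1 library held 13 of its cells.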

Results

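Single-cell transcriptomes were collected from the choroid and retinal pigment epithelium (RPE) of wild-type ICR mice, an outbred strain, at 8 weeks of age. The choroid is the vascular layer behind the retina, and the RPE is the pigmented epithelium that separates it from the photoreceptors. The study comprised 1 group of 2 droplet libraries, and each library pooled cells of 1 male and 1 female mouse. The libraries were used as replicates (n = 2), and no treatment or genotype was compared. The comparisons were between cell types within these libraries: which cell types carried the transcripts of vessel growth, matrix, complement and disease-locus genes, and how these genes differed between the arterial, capillary and venous endothelium. The first library held 91741168 UMIs and the second 149570817. After filtering, 8266 and 12674 cells remained, with medians of 7666 and 7913 UMIs and of 2333.5 and 2616 genes per cell. The second count lies above the 10000 cells that were loaded per library according to the labels. The p-values below measure only how differences between classes vary between these libraries, which are pools of separate mice. A shift common to all classes of a library is removed as a block, and all classes share the estimate of spread.

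Fibroblast-like cells made up 49.6% ± 1.61 of the cells (SD, n = 2) and were the largest class in both libraries. Melanocyte-like cells followed with 14.3% ± 0.614, mural-like cells (pericytes and smooth muscle) with 13.7% ± 0.945, macrophage-like cells with 5.76% ± 0.887 and endothelial-like cells with 5.51% ± 0.768. RPE-like cells made up 5.11% ± 2.21. Their share was 3.54% in the first library (exact 95% binomial interval 3.16% to 3.97%) and 6.68% in the second (6.25% to 7.12%). The intervals of the libraries, which cover counting error only, did not overlap for RPE-like, fibroblast-like, macrophage-like, endothelial-like, keratin epithelial-like and unnamed cells. T and NK-like cells made up 0.908% ± 0.121, Schwann-like cells 0.8997% ± 0.0450, B-like cells 0.732% ± 0.231, dendritic-like cells 0.702% ± 0.0342 and rod-like cells 0.406% ± 0.0614. Keratin epithelial-like cells (0.323% ± 0.235) numbered 13 in the first library and were not tested, and 2.16% ± 0.660 of the cells stayed unnamed. Several named clusters were led by stress or immune genes. These were fibroblast-like clusters with the interferon-induced genes Ifit1 and Ifit3 or with Cxcl5, Csf3 and Il11, and macrophage-like clusters with Il10, Cxcl2, Tnf and Il12b. The fibroblast-like share was 25.7% with an earlier form of the naming rule and 30.2% with a minimum of 500 UMIs, where 19.6% and 13.1% of the cells in the libraries stayed unnamed. The fibroblast-like class includes clusters of 2113 and 1018 cells with the chondrocyte marker Chad among their top 10 genes.

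**Figure D1:**
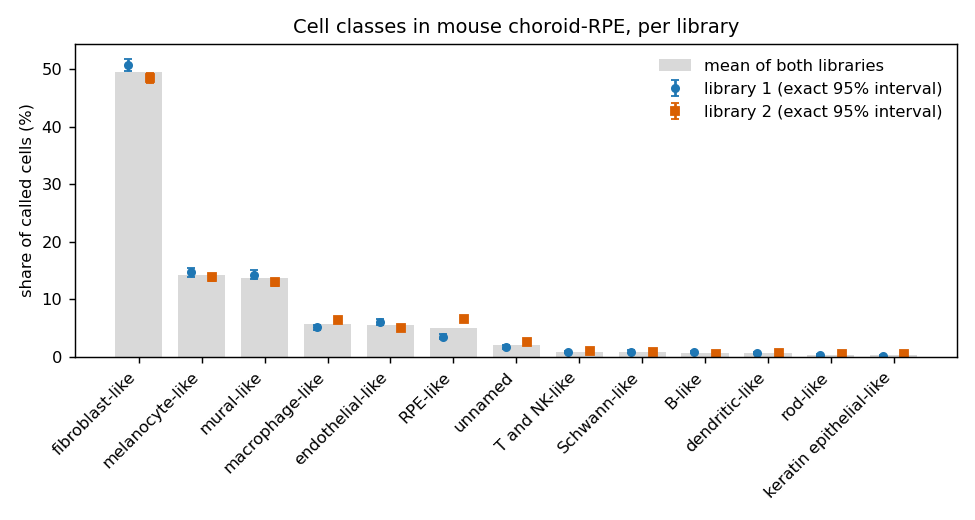
Share of each class among all called cells (percent, vertical axis). Points are the 2 libraries with exact 95% binomial intervals, grey bars are their mean, and fibroblast-like cells lead with 49.6%.

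Of the 220 panel genes tested, 135 were higher in fibroblast-like cells than in the mean of the other classes and 4 were lower (Vegfb, Kit, Ednrb and C3ar1). In endothelial-like cells 111 were higher and 27 lower, and in mural-like cells 109 and 12. RPE-like cells had 58 higher and 64 lower, macrophage-like cells 51 and 52, and melanocyte-like cells 40 and 73. Panel genes were higher more often than tested genes as a whole in fibroblast-like cells (61.4% against 22.8%), endothelial-like cells (50.5% against 18.1%) mural-like cells (49.5% against 18.7%), Schwann-like cells (20.5% against 11.2%), rod-like cells (16.4% against 7.80%), macrophage-like cells (23.2% against 18.7%) and T and NK-like cells (11.8% against 9.50%). They were not in RPE-like cells (26.4% against 28.2%), melanocyte-like cells (18.2% against 19.4%), dendritic-like cells (12.3% against 13.1%) and B-like cells (3.64% against 6.97%), and the differences in share were not tested. Rod-like and T and NK-like cells also carried fibroblast markers. Their median per raw UMI total was 0.229 and 0.153 of the fibroblast-like level in rod-like cells, and 0.0748 and 0.222 in T and NK-like cells. What such RNA adds to their counts was not tested. Counts adjusted over the list alone were 135 higher and 4 lower for fibroblast-like cells, 112 and 27 for endothelial-like cells, 111 and 12 for mural-like cells, 58 and 64 for RPE-like cells, 51 and 53 for macrophage-like cells and 40 and 73 for melanocyte-like cells. The class with the highest level was endothelial-like for 55 genes, mural-like for 37, fibroblast-like for 35, RPE-like for 29 and macrophage-like for 23. For 111 of the 220 genes the highest class also exceeded the class next to it, and for 190 the same class was highest in both libraries. The list counts given below for single classes were the same when adjusted over the list alone, unless the other count is given. Genes named below only to spell out such counts were chosen after their values were seen. Fold changes over the mean of the other classes are averages of logs in which sparse classes weigh as much as large ones, so levels and the difference to the next class are given below. The next class is the one next in fitted log level. For Ptprb, Tek, Kdr, Flt1, Bmp7, C1qc, Slc16a8, Slc4a5, Robo4 and Ccl7, a class of fewer than 200 cells had a higher mean CPM than that next class, and most or all of its UMIs came from 1 library.

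Within the angiopoietin and TIE pathway, which controls vessel stability, the receptors and Angpt2 were highest in endothelial-like cells and Angpt1 stood highest in fibroblast-like cells. Tek (TIE2, the angiopoietin receptor; ENSMUSG00000006386, GRCm38 chromosome 4, 94739289 to 94874976) reached 164 CPM ± 23.0 (UMIs scaled to library size; mean and SD, n = 2) in endothelial-like cells against 2.69 ± 0.522 in fibroblast-like cells, the next class (log2 difference 5.94 ± 0.31, SE; adjusted p = 4.50e-11). Tie1, the related orphan receptor (ENSMUSG00000033191, chromosome 4, 118471191 to 118490061), stood at 380.5 CPM ± 55.2 against 20.9 ± 1.15 in mural-like cells (4.20 ± 0.42; adjusted p = 2.68e-06). Ptprb (VE-PTP, a phosphatase that acts on TIE2; ENSMUSG00000020154, chromosome 10, 116275523 to 116389535) stood at 799 CPM ± 212 against 4.81 ± 3.02 in fibroblast-like cells (7.47 ± 0.33; adjusted p = 5.86e-13). Angpt2, the context-dependent ligand (ENSMUSG00000031465, chromosome 8, 18690263 to 18741562), was also highest in endothelial-like cells with 193 CPM ± 13.2, above mural-like cells with 57.7 ± 3.38 (1.74 ± 0.20; adjusted p = 2.03e-08). Angpt1, the activating ligand of TIE2 (ENSMUSG00000022309, chromosome 15, 42424723 to 42676977), stood at 336 CPM ± 88.4 in fibroblast-like cells, 81.4 ± 0.917 in T and NK-like cells, 65.5 ± 7.49 in mural-like cells and 8.76 ± 7.95 in endothelial-like cells. Against the mean of the other classes Angpt1 was higher in fibroblast-like cells (4.04 ± 0.36; adjusted p = 2.96e-06) and in mural-like cells (1.47 ± 0.45; adjusted p = 0.0225), and lower in endothelial-like cells (-1.71 ± 0.63; adjusted p = 0.0479).

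The class next to fibroblasts for Angpt1 was rod-like, with 100.0 CPM ± 74.99 from 30 and 57 cells, and the difference did not pass the test (1.92 ± 0.82; adjusted p = 0.0615). Per raw UMI total, which is another scale than the CPM given here, fibroblast markers stood at a median of 0.229 and 0.153 of their fibroblast-like level in these rod-like cells, and Angpt1 at 0.783 and 0.167. Svep1, a large matrix protein (ENSMUSG00000028369, chromosome 4, 58042442 to 58206859), was highest in fibroblast-like cells with 150.3 CPM ± 30.1, above rod-like cells with 27.0 ± 21.5 (2.77 ± 0.42; adjusted p = 1.74e-06). In the 2 fibroblast-like clusters with Chad among their top 10 genes, chosen after the data were seen, Svep1 stood at 299 ± 41.9 and 275 ± 40.8. In the other fibroblast-like clusters it lay between 14.6 and 90.1 CPM. Angpt4 (ENSMUSG00000027460, chromosome 2, 151911210 to 151945337) was too sparse to test. It had 54 and 154 UMIs in fibroblast-like cells, 2 and 3 in macrophage-like cells, 0 and 3 in mural-like cells and none in the other classes tested. Of the 6 members tested, 4 were higher and 2 lower in endothelial-like cells, 3 were higher in fibroblast-like cells (Angpt1, Svep1 and Tek), 3 in mural-like cells (Angpt1, Angpt2 and Tie1), 2 in T and NK-like cells (Ptprb and Svep1) and 1 in rod-like cells (Svep1). Few UMIs lay behind Ptprb (0 and 16) and Svep1 (5 and 7) in T and NK-like cells and Svep1 (8 and 4) in rod-like cells. In T and NK-like cells, fibroblast markers stood at a median of 0.0748 and 0.222 of their fibroblast-like level per raw UMI total.

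**Figure D2:**
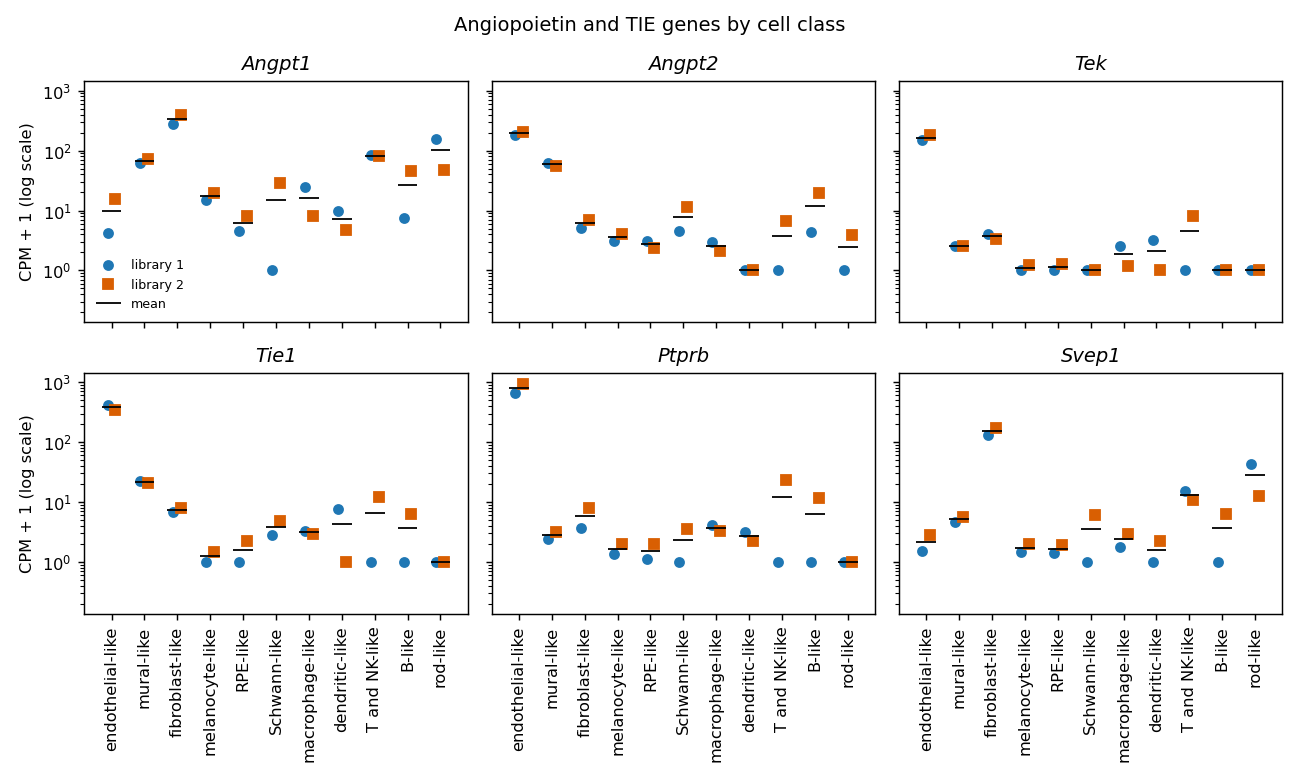
Expression of 6 angiopoietin and TIE genes in each class (CPM plus 1, logarithmic axis). Points are the 2 libraries and lines their mean, and Tek reaches 164 CPM in endothelial-like cells and 2.69 in fibroblast-like cells.

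The VEGF receptors were highest in endothelial-like cells. Flt1 (VEGFR1) stood at 2720 CPM ± 549 in endothelial-like cells against 11.5 ± 2.57 in mural-like cells, Kdr (VEGFR2) at 1066 ± 241 against 6.63 ± 3.27 in macrophage-like cells, and Flt4 (VEGFR3) at 179 ± 3.45 against 4.20 ± 1.94 in T and NK-like cells, with log2 differences of 7.90 ± 0.81, 7.51 ± 0.46 and 5.23 ± 0.43 (SE) and adjusted p-values of 5.11e-06, 1.09e-08 and 5.59e-11. Vegfa, chosen after its values were seen, was higher than in the mean of the other classes in RPE-like (243 CPM ± 52.0), fibroblast-like (223 ± 16.4) and mural-like cells (172 ± 7.76), and stood at 51.8 ± 0.629 in endothelial-like cells. The difference between its 2 highest classes did not pass the test (0.10 ± 0.34; adjusted p = 0.821). Of 9 VEGF genes tested, 7 were higher and 1 (Vegfb) lower in endothelial-like cells, and 6 were higher and 1 (Vegfb) lower in fibroblast-like cells.

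Pdgfb, Pdgfrb and Pdgfra each had another highest class. Pdgfb, which recruits mural cells, was highest in macrophage-like cells with 307 CPM ± 90.1, above endothelial-like cells with 99.8 ± 3.58 (1.61 ± 0.37; adjusted p = 0.00335). Its receptor Pdgfrb was highest in mural-like cells with 479.6 CPM ± 18.7, above fibroblast-like cells with 207 ± 5.08 (1.21 ± 0.25; adjusted p = 0.000315). Pdgfra was highest in fibroblast-like cells with 294 CPM ± 53.4 against 67.6 ± 40.5 in T and NK-like cells (2.29 ± 0.51; adjusted p = 0.00167). Of 6 PDGF genes, 4 were higher in fibroblast-like cells, 3 in endothelial-like cells, 3 in mural-like cells and 3 in macrophage-like cells, where 2 were lower (Pdgfd and Pdgfrb).

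In the Notch list, which covers arterial specification and mural contact, 8 of 12 genes were higher and 1 (Notch2) lower in endothelial-like cells, 7 were higher in mural-like cells and 7 in fibroblast-like cells. The endothelial ligand Dll4 stood at 142 CPM ± 21.0 in endothelial-like cells against 1.39 ± 1.97 in T and NK-like cells (adjusted p = 2.77e-10), where it had 0 and 2 UMIs. Jag2 stood at 82.1 CPM ± 18.3 against 12.2 ± 1.89 in dendritic-like cells (2.74 ± 0.33; adjusted p = 3.92e-08), and the receptor Notch4 at 64.6 ± 5.70 against 4.36 ± 1.10 in Schwann-like cells (3.85 ± 0.43; adjusted p = 1.28e-08).

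Bmp4, Bmp6 and Bmp7, bone morphogenetic proteins, were highest in RPE-like cells. Bmp4 stood at 493 CPM ± 18.4 in RPE-like cells against 59.4 ± 13.8 in endothelial-like cells (3.07 ± 0.22; adjusted p = 1.37e-12), Bmp6 at 85.4 ± 9.60 against 26.8 ± 1.03 in endothelial-like cells (1.67 ± 0.19; adjusted p = 1.46e-08), and Bmp7 at 56.8 ± 1.82 against 0.647 ± 0.158 in melanocyte-like cells (6.46 ± 0.30; adjusted p = 9.04e-16). Of 17 TGF-beta and BMP genes, 6 were higher and 8 lower in RPE-like cells, 12 were higher in fibroblast-like cells with none lower, and 11 were higher in endothelial-like cells with 2 lower (Bmpr1a and Tgfb3). In the Wnt and norrin list, 14 of 17 tested genes were higher in fibroblast-like cells and none lower. The secreted Wnt antagonist Sfrp5 was highest in RPE-like cells with 62.3 CPM ± 4.95 against 28.8 ± 2.78 in Schwann-like cells (1.12 ± 0.31; adjusted p = 0.00260). Wnt6 was highest in Schwann-like cells with 25.6 ± 1.75 against 2.89 ± 0.114 in fibroblast-like cells (3.14 ± 0.47; adjusted p = 1.47e-06). The transcription factor Lef1 was highest in T and NK-like cells with 154 ± 111 against 65.6 ± 8.31 in endothelial-like cells (1.09 ± 0.41; adjusted p = 0.0358), with 232 and 75.2 CPM in the libraries.

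Macrophage-like cells carried complement receptors and C1q, the recognition unit of the classical pathway. C5ar1 stood at 483 CPM ± 34.5 in macrophage-like cells against 16.2 ± 1.42 in dendritic-like cells (4.86 ± 0.45; adjusted p = 2.84e-07), C1qc at 3071 ± 240.3 against 53.8 ± 30.0 in dendritic-like cells (5.81 ± 1.04; adjusted p = 0.000510), with 46 and 3 UMIs in rod-like cells, and C3ar1 at 690.3 ± 108 against 17.3 ± 20.3 in rod-like cells (5.77 ± 0.49; adjusted p = 2.34e-09). Of 19 complement genes tested, 10 were higher and 5 lower in macrophage-like cells, and 10 were higher and 1 (C3ar1) lower in fibroblast-like cells.

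RPE-like cells had more of the genes near loci for age-related macular degeneration than any other class, with 16 of 30 tested higher and 2 lower (Adamts9 and Tgfbr1), against 13 higher in fibroblast-like cells, with none lower, and 11 higher and 4 lower in endothelial-like cells. No test compared these counts. Over all tested genes, 28.2% were higher in RPE-like, 22.8% in fibroblast-like and 18.1% in endothelial-like cells. RPE-like cells led in that share too, so the count does not set them apart for this list. The lactate transporter Slc16a8 stood at 2666 CPM ± 196 in RPE-like cells against 8.33 ± 2.46 in endothelial-like cells (8.34 ± 0.78; adjusted p = 2.26e-06), the cation channel Trpm3 at 1551 ± 22.7 against 16.8 ± 7.75 in T and NK-like cells (6.52 ± 0.43; adjusted p = 8.41e-10), and the collagen chain Col4a3 at 132 ± 23.6 against 47.6 ± 21.5 in mural-like cells (1.54 ± 0.22; adjusted p = 7.64e-07). Timp3 and Htra1, both chosen after their values were seen, had other patterns. Timp3, an inhibitor of matrix proteases, was higher than in the mean of the other classes in endothelial-like (5552 CPM ± 810.1), fibroblast-like (3519 ± 1001) and RPE-like cells (3269 ± 184), and Htra1, a secreted protease, was highest in fibroblast-like cells with 211 ± 31.2 against 93.3 ± 8.32 in mural-like cells (1.17 ± 0.37; adjusted p = 0.0158).

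Basement membrane and elastic matrix genes were spread over the stroma and the vessel wall. Of 25 tested, 19 were higher in fibroblast-like cells, 19 in mural-like cells with 1 lower (Fbln5), 16 in endothelial-like cells with 3 lower (Efemp1, Lama2 and Timp2) and 14 in Schwann-like cells. RPE-like cells had 9 higher and 9 lower, and macrophage-like cells none higher and 14 lower. Col4a4 was highest in RPE-like cells with 169 CPM ± 18.1 against 57.5 ± 11.6 in mural-like cells (1.58 ± 0.18; adjusted p = 1.22e-08), next to Col4a3 above, its partner in the collagen IV network. Lama3 was highest in endothelial-like cells with 15.5 ± 6.44 against 3.84 ± 0.0304 in fibroblast-like cells (2.00 ± 0.26; adjusted p = 4.99e-07). Among 19 vasoactive genes, 13 were higher and 1 (Ednrb) lower in fibroblast-like cells, 11 were higher in mural-like cells, and 9 were higher (10 when adjusted over the list alone) and 5 lower in endothelial-like cells. Nos3, endothelial nitric oxide synthase, stood at 229 CPM ± 9.50 in endothelial-like cells against 7.88 ± 4.20 in dendritic-like cells (4.99 ± 0.40; adjusted p = 4.26e-11). Nos1, the neuronal form, stood at 18.1 ± 2.67 in RPE-like cells against 0.630 ± 0.0434 in endothelial-like cells (4.85 ± 0.40; adjusted p = 1.57e-10), and the angiotensin receptor Agtr1a at 14.2 ± 1.35 in mural-like cells against 4.13 ± 1.10 in fibroblast-like cells (1.78 ± 0.25; adjusted p = 5.03e-07).

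Of 19 transport genes, 11 were higher and 1 lower in endothelial-like cells and 10 were higher and 1 lower (Slc16a3) in RPE-like cells. Gpihbp1, the endothelial anchor of lipoprotein lipase, stood at 90.8 CPM ± 23.8 in endothelial-like cells (adjusted p = 1.71e-14), and the next class, macrophage-like, had 1 UMI in each library. The bicarbonate transporter Slc4a5 stood at 562 ± 50.1 in RPE-like cells against 3.58 ± 0.864 in endothelial-like cells (7.38 ± 0.43; adjusted p = 7.77e-10). Of 17 guidance genes, 14 were higher in endothelial-like cells, 14 in fibroblast-like cells and 10 in mural-like cells (11 when adjusted over the list alone), with none lower. Robo4, an endothelial receptor, stood at 213 CPM ± 18.2 in endothelial-like cells and had 2 and 3 UMIs in macrophage-like cells, the next class (adjusted p = 9.04e-16). Sema3g stood at 40.8 ± 13.5 in endothelial-like cells against 4.61 ± 1.08 in Schwann-like cells (3.20 ± 0.52; adjusted p = 8.07e-06), and Sema3e at 33.6 ± 19.6 in Schwann-like cells against 1.82 ± 0.517 in fibroblast-like cells (4.16 ± 0.42; adjusted p = 3.08e-09).

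Of 21 chemokine, cytokine and growth factor genes, 17 were higher and 1 (Kit) lower in fibroblast-like cells, 15 higher in mural-like cells and 10 higher and 5 lower in macrophage-like cells. Adjusted over the list alone, the counts were 16 higher in mural-like cells and 10 higher and 6 lower in macrophage-like cells, and the same in fibroblast-like cells. RPE-like cells had 2 higher (Ackr3 and Csf1r) and 15 lower. The macrophage-like class led for the fractalkine receptor Cx3cr1 with 302 CPM ± 26.2 against 13.6 ± 6.90 in dendritic-like cells (4.47 ± 0.36; adjusted p = 2.27e-10), for Csf1r, the receptor of colony-stimulating factor 1, with 667 ± 140.1 against 70.5 ± 9.31 in RPE-like cells (3.24 ± 0.37; adjusted p = 8.57e-06), and for the chemokine Ccl7 with 6690.5 ± 2929 against 394 ± 158 in fibroblast-like cells (4.07 ± 1.26; adjusted p = 0.0156), while rod-like cells had 223 and 10 UMIs of Ccl7. Of 14 immediate early and dissociation stress genes, 8 were higher in macrophage-like cells, 8 in mural-like cells and 5 in endothelial-like cells, with none lower in these. In RPE-like cells 1 (Jun) was higher and 6 were lower, and in melanocyte-like cells 1 (Fosb) was higher and 7 were lower. Zfp36, an inducible gene that destabilises cytokine transcripts, was highest in macrophage-like cells with 1882 ± 124 against 615 ± 118 in dendritic-like cells (1.63 ± 0.44; adjusted p = 0.00664). Digestion took 2 h in collagenase and 30 min in trypsin, so levels of these stress genes and of induced cytokines hold for dissociated cells.

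**Figure D3:**
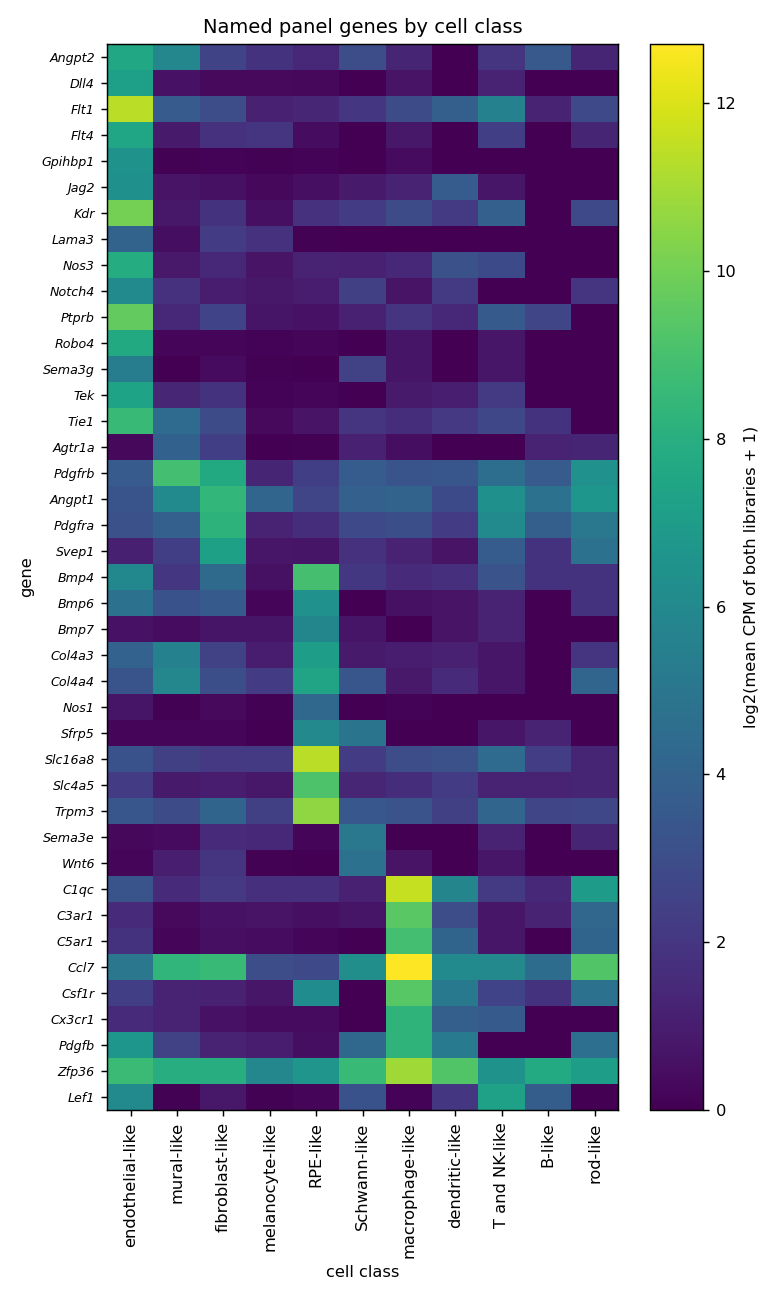
Expression of the named genes (rows) in each class (columns) as log2 of the mean CPM of 2 libraries plus 1. Brighter colour is higher, and the VEGF receptors Flt1, Kdr and Flt4 stand out in the endothelial-like column with 2720, 1066 and 179 CPM.

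The endothelium was split into arterial (42 and 68 cells), capillary (267 and 336) and venous beds (61 and 71). Angpt2 stood at 237 CPM ± 32.3 in capillary-like and 146 ± 60.5 in venous-like cells, and had 3 and 4 UMIs in arterial-like cells, where it was lower (7.17 ± 0.387 CPM; adjusted p = 4.85e-07). The chemokine Cxcl12 stood at 695 ± 12.9 in arterial-like, 295 ± 48.6 in capillary-like and 21.8 ± 6.02 in venous-like cells, and was lower in the venous bed (-4.41 ± 0.49; adjusted p = 2.88e-05). The elastic fibre gene Fbln5 stood at 201 ± 5.21 in arterial-like and 169 ± 20.4 in venous-like cells and at 8.14 ± 3.03 in capillary-like cells, where it was lower (-4.54 ± 0.30; adjusted p = 4.87e-10). Sema3g was higher in arterial-like cells, with 189 ± 53.3 against 35.0 ± 11.2 in capillary-like cells (adjusted p = 3.74e-09), and had 1 UMI per library in venous-like cells. The lipid transporter Mfsd2a was higher in arterial-like cells with 17.6 ± 1.16 CPM from 8 and 9 UMIs (adjusted p = 9.13e-05). The arterial-like cluster also raised 3 retinal endothelial markers, as did some capillary-like clusters. The levels of Angpt2 and Mfsd2a were in view while the bed naming was revised, so the beds were not named blind to these genes.

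Sema3c and Npr3, the natriuretic peptide clearance receptor, had no UMI in venous-like cells of either library. They were at least 23.7-fold and at least 19.0-fold lower there than in the mean of the other beds, against a floor of 3 counts over both libraries (1.99 CPM; adjusted p = 3.85e-06 and 2.06e-05). Sema3c stood at 43.2 CPM ± 13.7 in arterial-like and 51.1 ± 8.31 in capillary-like cells, and Npr3 at 25.3 ± 19.5 and 50.1 ± 16.96. Both were called higher in arterial-like cells (log2 5.53 ± 1.07 and 4.84 ± 1.33), although their mean levels lay below those of capillary-like cells. The mean of the other beds averages logs and includes the venous bed without UMIs, so these arterial values are no measure of arterial enrichment. The activin subunit Inhba was found in venous-like cells with 58 and 33 UMIs and in neither other bed, at least 205-fold higher against the same kind of floor (0.310 CPM; adjusted p = 0.00274). Sema3a was higher in venous-like cells with 28.2 ± 3.48 CPM against 1 and 6 UMIs in capillary-like cells (adjusted p = 6.07e-06). Col4a4, with 9.87 ± 4.40 CPM, and the fatty acid receptor Cd36 were higher in capillary-like cells (adjusted p = 0.000135 and 0.0271), and Cd36 was carried mostly by the second library with 86.1 CPM against 6.49. Ccl2 was higher in venous-like cells with 198 CPM ± 234, from 32.2 and 363 CPM in the libraries (adjusted p = 0.0492). Few UMIs lay behind Nos1 in arterial-like cells (3 and 4; adjusted p = 0.00252), Tslp in venous-like cells (4 and 2; adjusted p = 0.0242) and Pdgfc in venous-like cells (1 and 5; adjusted p = 0.0494).

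Of 210 panel genes tested in the beds, 33 were higher and 16 lower in arterial-like cells, 31 and 17 in capillary-like cells, and 28 and 32 in venous-like cells. The counts adjusted over the list alone were 37 and 16, 33 and 19, and 31 and 36. A further 284 endothelial-like cells stayed without a bed, among them 198 that had raised Vwf, Selp, Vcam1 and Lrg1 together with RPE genes, so the venous bed covers 132 cells. With a finer second clustering the venous name went to 104 cells without a bed before and to 48 of the 132. A cluster of 90 cells with 6 venous markers raised stayed unnamed through 1 marker of another type among its top 10 genes. The values below thus compare other cells, and do not show that the cells first named venous-like lack these differences. The venous values of Inhba, Sema3c and Tslp and the arterial values of Sema3c and Npr3 shrank to log2 values between -0.24 and 0.0372, with the sign changed. None of these passed the test any longer, nor did Sema3c in capillary-like and Ccl2 in venous-like cells. Tslp, Pdgfc and arterial Npr3 did not pass without the library block, and Cd36, Ccl2 and arterial Npr3 did not pass with free RNA subtracted. In these alternatives, the fold changes of the genes that did not pass stayed about as large or grew. Their SE was larger except for Pdgfc, where it was nearly unchanged.

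**Figure D4:**
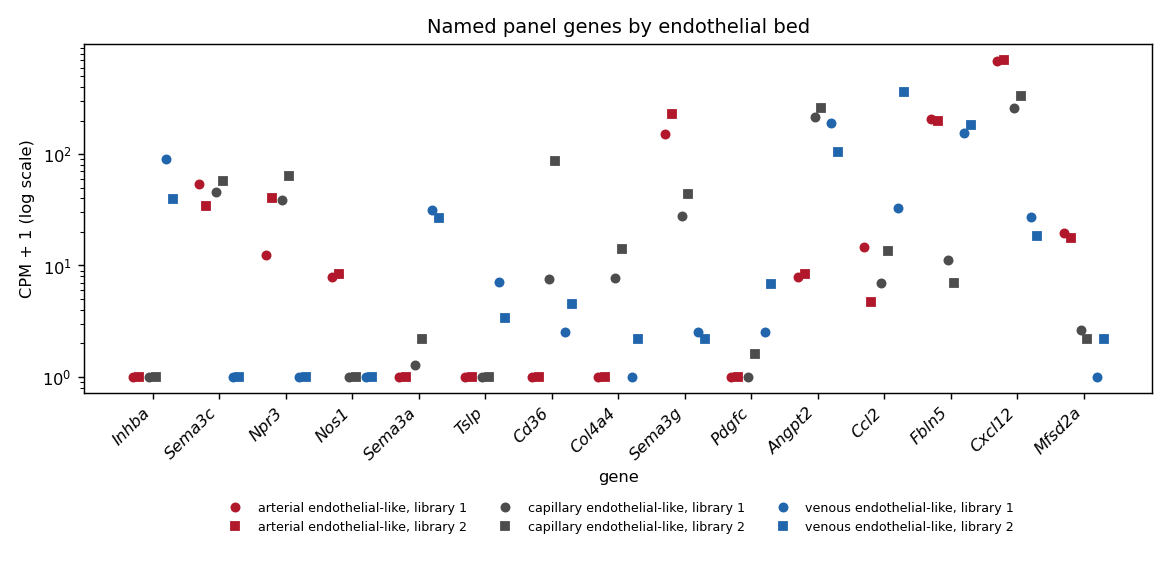
Expression of the named bed genes in arterial-like, capillary-like and venous-like cells (CPM plus 1, logarithmic axis). Points are the 2 libraries, and Cxcl12 stands at 695 CPM in arterial-like and 21.8 in venous-like cells.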

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

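The Sox10 test was chosen only after its result was seen, and the test of free RNA in endothelial-like cells only after their leading genes were seen. The other tests of this part were set out before the values they measure were seen. The design names no group that would give a biological explanation, so none was tested. Levels and ratios in this part are per raw UMI total. Cells left unnamed entered no comparison, and 6 such groups of cells had leading genes far above the level of the other cells.

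The largest held 247 cells, led by Pcp4 (939 CPM ± 215, SD, n = 2), Crhbp, Aldoc and Folr1 (848 ± 29.4), with Pax6 (258 ± 173), Optc (158 ± 113) and pigment genes. Sox10 cannot decide on melanocyte doublets, since it was picked from 7 melanocyte markers after its level was seen. It stood at 0.139 or less of the median ratio to melanocyte-like cells that the other 6 reached, in both libraries. Against the lowest of these ratios it stood at up to 0.506. Doublets with melanocytes or of other cells stay open, since the median doublet score lay at least 0.0451 above that of melanocyte-like cells in both libraries.

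Another 200 cells were led by S100a9 (3085 CPM ± 1427), S100a8 (1862 ± 783), F10 and Chil3, which are myeloid genes, and 26 cells by the cell division genes Prc1 (717 ± 509), Cenpf, Anln and Ube2c.

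Among endothelial-like cells, 198 carried the RPE genes Ttr (1734 CPM ± 716), Rpe65 (141 ± 91.7), Rgr and Trf together with raised Vwf, Selp, Vcam1 and Lrg1. Free RNA alike in all droplets was argued against as the whole source, because fibroblast, melanocyte and rod markers, which it also holds, rose less than the RPE markers. These cells were picked for leading RPE genes, which favours this outcome, and the rod list had only 9 and 11 UMIs in them. Against capillary-like cells the RPE list stood 82.0-fold and 12.9-fold higher in the 2 libraries, the melanocyte list 2.84-fold and 1.39-fold, the fibroblast list 1.44-fold and 2.95-fold and the rod list at 0.711 and 0.848, and the median of these 3 was at most 0.108 of the RPE value in both libraries. A part from free RNA stays open. Doublets of an endothelial and an RPE cell were argued against too: the RPE markers reached a median of 0.0343 of the RPE-like level or less. RPE fragments attached to these cells were not tested.

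A further 52 endothelial-like cells were led by the fibroblast genes Dcn (1892 CPM ± 786), Lum, Col1a2 and Col1a1, and 34 by Lyz2 (707 ± 367), Ccl4, Dct (2160.5 ± 585) and Il1b, which belong to macrophages and melanocytes.

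Angpt1 in rod-like and T and NK-like cells was the third pattern weighed, because it decides whether fibroblasts stand apart for this ligand. Fibroblast RNA carried by these cells stays open. The median fibroblast marker ratio was 0.293 of the Angpt1 ratio in rod-like and 0.224 in T and NK-like cells in 1 library, and close to it in the other, with 16 to 58 UMIs of Angpt1 per library. Free RNA at the share estimated from rod genes was argued against as the whole source in T and NK-like cells. At least 89.8% of their Angpt1 UMIs were left after its subtraction. That share was 2.02% and 8.17%, and free RNA held Angpt1 at 68.3 and 114 CPM, so the outcome was nearly fixed by the share. The estimate was also uneven between libraries, with 0.504% and 16.6% in dendritic-like cells. A larger share was not tested and stays open.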

How the results depend on the processing

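The stricter doublet removal, the earlier naming rule and the allowance of 1 foreign gene were chosen after seeing the data; the other alternatives, the gene lists and the tests across classes and beds were set before the data were examined. The total of higher calls across classes, the counts of higher panel genes in endothelial-like, mural-like, fibroblast-like, melanocyte-like, RPE-like and macrophage-like cells, the count of genes whose highest class passed over the next and that of bed calls stayed within 1.5 times their values under the alternatives run for each. In rod-like cells the lower genes went from 6 to 3 with DESeq2 size factors. Of 646 higher calls (pairs of gene and class), 518 (a minimum of 3000 UMIs, with 9 classes) to 646 (1 foreign gene allowed) were called again. Of 157 bed calls, 102 (finer second clustering) to 155 (no filter on low counts) were called again. Without the library block, 623 of the 646 and 124 of the 157 were called again.

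The fibroblast-like share (49.6%) moved to 30.2% with a minimum of 500 UMIs, 36.6% and 40.2% with at most 10% and 40% mitochondrial UMIs, 34.6% with z-scoring, 36.9% with panel genes in the clustering, 47.7% without doublet removal, 47.7% and 47.3% at resolutions 0.5 and 2.0, and 25.7% with the earlier mixed rule. A large fibroblast cluster lost its name through 1 foreign marker in several of these. With 1 foreign gene allowed the share was 44.1% at 500 UMIs, 47.1% with panel genes, 47.7% without doublet removal and 47.7% at resolution 0.5, and within 1 SD of 49.6% for the other alternatives run. Each library alone gave 48.4% to 50.7%.

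At resolution 1.0 of the second clustering, the differences were lost for Inhba (log2 -0.0452), Sema3c (0.0372 ± 0.37, SE) and Tslp (-0.12) in venous-like cells. They were lost too for Sema3c (-0.19 ± 0.39) and Npr3 (-0.24 ± 0.57) in arterial-like cells. The signs of these values changed, but none passed the test, and Inhba and Tslp had no SE. Of 132 venous-like cells, 48 kept that name and 84 became unnamed, while 104 unnamed cells became venous-like and a retinal-like bed entered. A cluster of 90 cells with 6 venous markers raised stayed unnamed there, through 1 marker of another type among its top 10 genes. Sema3c in capillary-like (0.16) and Ccl2 in venous-like cells (0.63) no longer passed. Without the library block, Tslp (log2 7.90 ± 2.21 before and 7.91 ± 3.06 after; adjusted p = 0.198), Pdgfc (5.68 ± 1.80 and 5.67 ± 1.81; 0.0841) and Npr3 in arterial-like cells (4.84 ± 1.33 and 4.84 ± 1.51; 0.0911) missed the threshold. The arterial Npr3 value is set against a mean of logs with the venous bed without UMIs. Its level was 25.3 CPM, against 50.1 in capillary-like cells. With free RNA subtracted, Cd36 (7.65 ± 1.98 and 7.63 ± 2.20; 0.0570), arterial Npr3 (4.81 ± 1.62; 0.113) and Ccl2 (4.54 ± 1.31 and 13.66 ± 3.79; 0.0593) missed it. Without the block or with free RNA subtracted, none of these calls lost its fold change. The SE grew except for Pdgfc, where it was nearly unchanged. Ccl2 had few UMIs in arterial-like (6 and 2) and capillary-like cells (22 and 63), so its larger fold change is not read as a stronger difference. The cause of the other changes was not tested.

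Leaving out 1 library gives fold changes without a test: 607 to 620 calls across classes, 107 to 108 for highest over next, 144 to 149 in the beds, and higher genes of 110 to 111 in endothelial-like, 104 to 105 in mural-like, 128 to 134 in fibroblast-like, 34 to 40 in melanocyte-like, 55 to 56 in RPE-like and 48 to 49 in macrophage-like cells. Of 61 named values, 12 were the same under every alternative, and 81 single values moved, all with 1 library left out. Those values are computed from log2 CPM, and the cause of the moves was not tested. Total UMIs were lowest in rod-like cells among the classes tested (148572 and 226842) and in arterial-like cells among the beds (397048 and 471669), and what depth limits was not tested.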

Other observations

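The values and the test of this part were chosen after the data were seen.

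Within the fibroblast-like class, Angpt1 ranged from 673 CPM ± 127 (SD, n = 2) in a cluster of 1264 cells led by Crabp2 and Ephb1 to 18.3 ± 18.7 in 366 cells led by Kera and Thbs4. Tek stood at 38.9 ± 16.2 (72 and 78 UMIs) in 414 cells led by Clec3b, Dpt and Pi16, where Kdr stood at 16.3 ± 10.2 (13 and 67 UMIs), the highest of the 9 clusters, and Tie1 at 1.23 ± 0.244 (2 and 3 UMIs). In the other 8 fibroblast-like clusters Tek lay between 0 and 2.04 CPM. Tie1 was highest in 2662 fibroblast-like cells led by Tfpi2 and Tcf21, with 24.7 CPM ± 2.61 (103 and 229 UMIs). Svep1 was highest in clusters led by Ltbp2 (299 ± 41.9) and Angptl7 (275 ± 40.8), the 2 with Chad among their top 10 genes. It lay between 14.6 and 90.1 CPM in the other fibroblast-like clusters.

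Pericyte-like cells (1713) and smooth muscle-like cells (1117) were compared in edgeR over 15131 genes. Of 225 panel genes tested, 53 were higher in pericyte-like and 19 in smooth muscle-like cells. The collagen chain Col4a4 stood at 95.04 CPM ± 26.4 in pericyte-like against 8.64 ± 0.0124 in smooth muscle-like cells (log2 difference 3.50 ± 0.25, SE; adjusted p = 2.96e-14), and Agtr1a at 23.5 ± 4.19 against 2.03 ± 0.426 (3.62 ± 0.40; adjusted p = 2.58e-09). Lama5 was lower in pericyte-like cells, with 8.39 ± 1.06 against 115 ± 4.53 (-3.76 ± 0.26; adjusted p = 2.96e-14).

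Of cells with at least 2 UMIs of either Xist or Y-linked genes and none of the other, 40.1% and 29.2% carried the Y-linked ones in the 2 libraries. Cells with at least 2 UMIs of both made up 0.569% and 1.26% of all cells. The 13 keratin epithelial-like cells of the first library carried Xist alone.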
